A study of Mus musculus with 6 samples.

How the data were processed

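RNA was sequenced from mouse prostate in 6 libraries that the labels place in 3 groups of 2. The first group was prostate tumors of males that carried a humanised allele with 12 glutamines in a polyglutamine tract (12Q), and the second was tumors of males with the 48-glutamine allele (48Q). Both tumor genotypes also carried, per the labels, 1 β-catenin gene allele with a conditional exon 3 and the PB-Cre4 transgene, which expresses Cre recombinase in prostate epithelium. Loss of exon 3 removes the residues through which β-catenin is marked for degradation. The third group was normal prostate of wild-type mice (WT). Total RNA was extracted with RNA-Bee from fresh tumors or normal prostate, and libraries were made with the Kapa RNA HyperPrep kit, per the labels' protocols. Each sample was assigned to its group and replicate number from its label. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

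The deposited values are whole-number counts of reads per gene, with no normalization, in 1 table made by the authors for all 6 libraries. Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 2.0.14 and counted with HTSeq 0.6.0. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The number of table columns that matched no sample was 0. Of the 24091 gene symbols in the table, 23509 were found in the GENCODE M21 annotation of mm10, and 23446 of these (99.7%) overlapped the gene of that name, so that coordinates are printed as the table gives them, 1-based in mm10. Because the strand setting is unknown, values of genes whose exons overlap another M21 gene are uncertain. Among the genes named in the text these are Aldh1l2, Axin2, Ccna2, Ctnnb1, Gabra4, Glul, Krt5, Krt6a, Lef1, Lox, Notum, Pdgfra, Pkm, Rptn, Slc1a2, Tagln, Tgm4, Tnc and Top2a. Genes with near-identical copies are also uncertain, here Krt6a and the hemoglobin genes among the red blood cell genes.

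Library totals ranged from 26416181 to 28559546 counts. Genes with enough counts were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15050 genes. Counts were scaled by TMM (trimmed mean of M-values), and levels are given as CPM (edgeR's cpm, counts relative to the scaled library total), as mean ± SD. A count of 3 in a library corresponded to 0.0856 to 0.156 CPM. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) in 1 fit of the 3 groups with 3 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. The common dispersion was 0.143, a biological coefficient of variation of 0.378. Where every library of a group was at 0 counts, the fold is a lower bound computed with 3 counts per library in that group. Where a group held 1 to 3 counts in all, the ratio of CPM is given with an exact 95% interval. Such intervals and bounds cover counting error only.

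Groups of genes were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2, first with a preset correlation of 0.01 between genes and then with an estimated correlation, and with fry, all adjusted over the lists. fry asks whether the members of a list move on balance in 1 direction, without comparing them with other genes. The 32 lists were Wnt/β-catenin target genes, Wnt ligands and receptors, androgen-responsive genes, prostate secretory products, seminal vesicle secretions, luminal epithelium, basal epithelium, squamous keratinization, hair follicle genes, neuroendocrine markers, cell cycle genes, epithelial-mesenchymal transition factors, fibroblast and matrix genes, smooth muscle, skeletal muscle, adipocytes, macrophages, neutrophils, T and NK cells, B and plasma cells, endothelium, urothelium, red blood cells, sterol and fatty acid synthesis, interferon-stimulated genes, unfolded protein response, glycolysis and hypoxia genes, immediate early genes, IGF axis, Notch pathway, Hedgehog pathway and mitochondrially encoded genes. A list needed 3 tested members, which 31 lists had. Of the 13 mitochondrially encoded genes, 0 were in the table, so no mitochondrial share was computed.

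The design, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule took Ctnnb1 as a targeted gene, then per comparison the 8 largest increases and the 8 largest decreases among genes past the threshold with groups that did not overlap and a mean of at least 10 CPM in the higher group, leaving out predicted and clone names. It also took up to 4 members per list, those past the threshold with the smallest adjusted p, or the 2 members with the highest mean CPM where none passed. Genes outside this rule are said to have been chosen after their values were seen.

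Alternatives were DESeq2's size factors within edgeR, library totals in place of TMM, no low-count filter, a filter of CPM above 1 in 2 libraries, DESeq2 1.42.0, limma-voom, a fit of the 2 compared groups alone, the replicate number as a block, an adjusted p threshold of 0.01, an added 2-fold minimum, and each library left out in turn. Scaling to the 12 luminal genes and a crossed pairing were added after the data were seen. Where 1 library was left out, the remaining library of its group was assumed to vary like those of the other groups. Overlap between the tumor comparisons, which share their WT libraries, was set against 20 simulations of unchanged groups and against the overlap of independent lists.

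The steps were tested on simulated counts drawn from each gene's mean over the libraries, its dispersion and the libraries' depths, with 200 genes changed. In the simulation of 12Q against WT, run on 14754 genes, the test recovered 0% of genes changed 2-fold, 35.8% of those changed 4-fold and 74.2% of those changed 8-fold, with 6 false calls. In that of 48Q against WT, run on 14796 genes, the recovered shares were 0%, 32.8% and 68.2%, with 5 false calls. In that of 12Q against 48Q, run on 14738 genes, they were 0%, 34.3% and 75.8%, with 5 false calls. When the cell cycle list was raised 2-fold in these simulations, camera with the preset correlation gave adjusted p = 5.7e-15, 1.7e-14 and 2.4e-12 in the same order, while the estimated correlation gave 0.0810, 0.136 and 0.292 and so missed the raised list each time. Of the 30 other lists, 1, 0 and 1 passed with the preset correlation. Genes were drawn independently in these simulations, whereas the correlation estimated from the data was 0.601 for cell cycle and 0.901 for smooth muscle genes. The simulations therefore do not show how the preset correlation performs for correlated genes, and give no ground to set the estimated correlation aside. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.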

Results

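Gene expression in prostate tumors driven by stabilised β-catenin was measured by RNA sequencing in mice with a short (12Q) or a long (48Q) polyglutamine tract in a humanised gene, and in normal prostate of wild-type mice (n = 2 libraries per group). The series is about the effect of a short polyglutamine tract on tumors of the Wnt/β-catenin pathway, and the design gives 3 comparisons, each tumor genotype against WT prostate and 12Q against 48Q tumors. Libraries held 26416181 and 28559546 counts in 12Q, 27416387 and 28278522 in 48Q and 27082455 and 27882291 in WT. In WT prostate, 9530053A07Rik alone took 17.4% and 22.8% of all counts. It took 2.99% and 1.34% in 48Q tumors and 0.498% and 0.0580% in 12Q tumors. TMM factors were 0.708 and 0.811 in WT, 1.02 and 1.13 in 12Q and 1.21 and 1.24 in 48Q. Replicates correlated across genes at r = 0.947 in 12Q, 0.983 in 48Q and 0.955 in WT, and no pair agreed within sampling noise (chi-square per degree of freedom 277, 42.2 and 193), so no pair was treated as copies of 1 library. The first principal component held 55.4% of the variance and placed the 12Q libraries at -101 and -126, the 48Q libraries at 12.4 and -7.15 and the WT libraries at 107 and 115. In every gene called higher or lower by name, both libraries of 1 group lay above both of the other.

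Ctnnb1 (mm10, chromosome 9, 120933400 to 120960507), the β-catenin gene targeted in the tumors, was at 996 ± 54.2 CPM (counts scaled to library size) in 12Q, 1019 ± 88.0 in 48Q and 619 ± 70.7 in WT (SD, n = 2). It did not pass the test in 12Q (log2 fold change 0.69, edgeR adjusted p = 0.15) or 48Q (0.72, edgeR adjusted p = 0.208), nor between tumors (-0.03, edgeR adjusted p = 0.954), and its counts are uncertain because its exons overlap another gene. Counts per gene cannot show the deletion of exon 3, so these values do not check the genotypes.

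**Figure D1:**
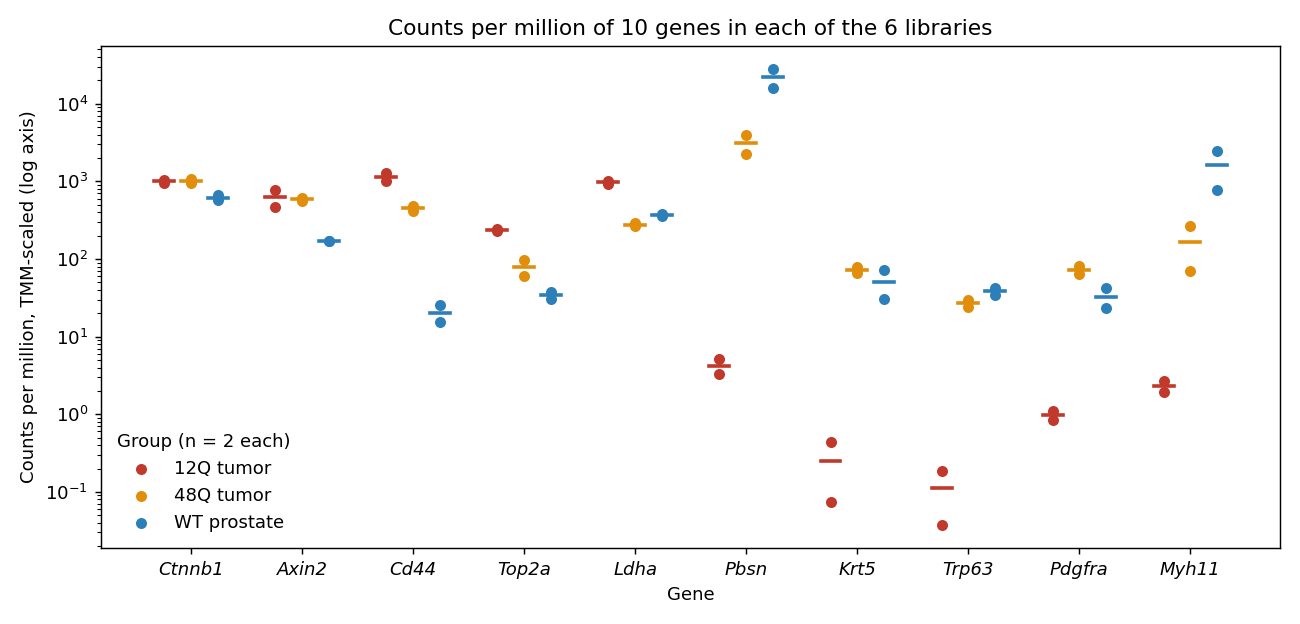
Points are CPM after TMM scaling on a log axis for 10 genes in each of the 6 libraries, colored by group, and bars are the means of the 2 libraries. Trp63 and Krt5 lie below 1 in both 12Q libraries and above 20 in the other 4.

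12Q tumors were compared with WT prostate to see how these tumors differ from normal prostate. WT mice differ from both tumor groups in the humanised allele, the β-catenin allele and PB-Cre4 as well as in the tumor. No tumor-free group carried these alleles, so the comparisons with WT cannot tell their effects apart. Of the targets of Wnt/β-catenin signalling 10 of 19 were called higher, and probasin, a major androgen-dependent secretion of the mouse prostate, was almost lost. Cd44 (chromosome 2, 102811142 to 102901665) stood at 1155 ± 202 CPM against 20.4 ± 7.32 in WT, 56.6-fold higher (edgeR adjusted p = 0.0027). Apcdd1 and Notum, which encode secreted or membrane inhibitors of Wnt signalling, rose to 563 ± 11.001 CPM from 11.2 ± 10.7 and to 49.4 ± 14.4 CPM from 2.09 ± 1.48 (edgeR adjusted p = 0.00823 and 0.00572). Of the 19 tested Wnt/β-catenin target genes, 10 were higher, 0 lower and 9 not past the threshold, and 14 were higher when adjusted over the list alone. The list passed upward with a median log2 fold change of 1.72 (camera adjusted p = 1.0e-05, and adjusted p = 0.505 with an estimated correlation). Of 25 Wnt ligands and receptors, 6 were higher, 4 lower and 15 not past (7 and 5 when adjusted over the list alone). Wnt4 was at 149 ± 20.03 CPM against 6.32 ± 3.32 and Ror1, a Wnt5a receptor, at 0.229 ± 0.114 against 3.77 ± 2.30, and the list itself did not pass (median 0.49, or 0.21 with bounded members, camera adjusted p = 0.565).

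Pbsn (chromosome X, 77837898 to 77853500), the probasin gene, stood at 4.23 ± 1.28 CPM in 12Q tumors against 22179 ± 8535 in WT (log2 fold change -12.35, edgeR adjusted p = 0.0031). Of 7 prostate secretory products, 1 was higher, 2 lower and 4 not past (1 and 3 when adjusted over the list alone), and the list did not pass by camera (median -2.97, camera adjusted p = 0.0737) but passed downward by fry (0.0189). Of 21 androgen-responsive genes, 4 were higher, 7 lower and 10 not past (4 and 9 when adjusted over the list alone). Abcc4 and Uap1 had log2 fold changes of -3.28 and -1.94, while Pmepa1, which encodes an inhibitor of TGF-β signalling, was at 56.5 ± 21.1 CPM against 7.72 ± 1.77, and the list did not pass by camera (median -0.91, camera adjusted p = 0.108) but passed downward by fry (0.0269). Ceacam10, counted among the secretory products, went the other way from Pbsn and was at least 157-fold higher than in WT, where it had 0 counts, a call lost without WT replicate 1 or WT replicate 2 (edgeR adjusted p = 0.111 and 0.113). Ceacam10 was at 22.7 ± 29.6 CPM, and its lower bound was 302-fold without 12Q replicate 1 and 11.8-fold without 12Q replicate 2.

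Several basal cell genes were almost absent from 12Q tumors. Trp63 (chromosome 16, 25683765 to 25892088), the p63 transcription factor of basal cells, was at 0.111 ± 0.105 CPM against 38.4 ± 6.35 in WT (log2 fold change -8.32, edgeR adjusted p = 0.0027), and Krt5, Krt15 and Col17a1, structural proteins of basal epithelium, had log2 fold changes of -7.58, -8.30 and -8.11. Without 12Q replicate 1 the values of Trp63, Krt5 and Krt15 were -7.61, -6.82 and -7.50. Without 12Q replicate 2, which left at most 3 counts in 12Q, their CPM ratios were 0.000954 (95% interval 2.4e-05 to 0.00533), 0.00140 (95% interval 0.000169 to 0.00506) and 0.000753 (95% interval 9.1e-05 to 0.00272). Without WT replicate 2 Krt5 was at -6.82. Of 12 basal genes, 1 was higher, 7 lower and 4 not past (1 and 7 when adjusted over the list alone), with a median of -3.17 (camera adjusted p = 0.0104, and adjusted p = 0.505 with an estimated correlation). The call of this list was lost without WT replicate 1 (camera adjusted p = 0.139). Among 12 luminal genes, 0 were higher, 1 lower and 11 not past, and the list did not pass (median -0.02, camera adjusted p = 0.763). Genes of keratinizing squamous epithelium passed upward as a list, with 9 of 17 higher, 1 lower and 7 not past (11 and 1 when adjusted over the list alone). The squamous median was 4.64, or 3.06 with bounded members (camera adjusted p = 5.4e-05, and adjusted p = 0.505 with an estimated correlation). Cnfn, a component of the cornified envelope, was at least 196-fold higher than in WT, where it had 0 counts, and Krt6a had a CPM ratio of 298 (95% interval 102 to 1448), or 484 (95% interval 86.7 to 19134) without WT replicate 1. Of 17 hair follicle genes, 7 were higher, 0 lower and 10 not past (9 and 0 when adjusted over the list alone). The hair follicle median was 4.67, or 2.95 with bounded members (camera adjusted p = 3.2e-06, and adjusted p = 0.505 with an estimated correlation). Dlx3, a transcription factor of the hair matrix, was at 89.3 ± 34.8 CPM against 0.277 ± 0.171. Among the largest increases of all genes, Rptn and Dsg4, which encode proteins of the cornified layer and of desmosomes in hair, were at least 693-fold and 488-fold higher than in WT, where both had 0 counts. The call of Rptn was lost without WT replicate 1 or WT replicate 2 (edgeR adjusted p = 0.0944 and 0.0954). Both genes varied between the 12Q libraries, with Rptn at 100.2 ± 128.8 CPM and Dsg4 at 70.6 ± 65.6. Without 12Q replicate 1 the bounds were 1324-fold for Rptn and 809-fold for Dsg4, and without 12Q replicate 2 they were 63.2-fold and 167-fold.

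Cell cycle genes rose almost as a whole, 28 of 29 being higher, 0 lower and 1 not past, the same counts as when adjusted over the list alone. Their median log2 fold change was 3.42 (camera adjusted p = 3.2e-15, and adjusted p = 0.505 with an estimated correlation), and Ccna2, which encodes cyclin A, was at 53.5 ± 6.21 CPM against 4.28 ± 0.957. Of 12 glycolysis and hypoxia genes, 9 were higher, 0 lower and 3 not past (9 and 0 when adjusted over the list alone). The glycolysis and hypoxia median was 2.13 (camera adjusted p = 4.5e-05, and adjusted p = 0.505 with an estimated correlation). Pkm, the muscle-type pyruvate kinase gene, was at 1088 ± 243 CPM against 205 ± 6.98. Of 9 immediate early genes, 5 were higher, 0 lower and 4 not past (5 and 0 when adjusted over the list alone). The immediate early median was 2.11 (camera adjusted p = 0.00135, and adjusted p = 0.505 with an estimated correlation). Egr1 was at 281 ± 11.3 CPM against 35.6 ± 8.27. Of 15 genes of the unfolded protein response, 0 were higher, 5 lower and 10 not past (0 and 8 when adjusted over the list alone). The unfolded protein response median was -2.11 (camera adjusted p = 0.00135, and adjusted p = 0.530 with an estimated correlation). Without WT replicate 1 the mean log2 fold change of this list was -0.98 in place of -2.02 (camera adjusted p = 0.0445). Creb3l1 fell by 3.39 on the log2 scale.

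Lists of markers of other cell types followed no single direction. All 10 smooth muscle genes were lower, also when adjusted over the list alone (median -6.28, camera adjusted p = 4.1e-07, and adjusted p = 0.505 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain gene, was at 2.29 ± 0.522 CPM against 1615 ± 1194. Of 16 fibroblast and matrix genes, 2 were higher, 4 lower and 10 not past (2 and 8 when adjusted over the list alone), and the list did not pass (median -1.26, camera adjusted p = 0.0737). Pdgfra, a receptor that marks fibroblasts, was at 0.983 ± 0.186 CPM against 32.8 ± 13.3, and Dpt, a matrix protein gene, was at least 296-fold lower, at 0 counts in 12Q (at least 184-fold without WT replicate 1). Of 5 skeletal muscle genes, 0 were higher, 3 lower and 2 not past (1 and 3 when adjusted over the list alone). The skeletal muscle median was -7.97 (camera adjusted p = 0.0339, and adjusted p = 0.506 with an estimated correlation). This call was lost without 12Q replicate 2, WT replicate 1 or WT replicate 2 (camera adjusted p = 0.175, 0.0555 and 0.0765).

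Macrophage genes passed upward as a list, with 7 of 11 higher, 1 lower and 3 not past (9 and 1 when adjusted over the list alone). The macrophage median was 1.94 (camera adjusted p = 0.00489, and adjusted p = 0.505 with an estimated correlation). C1qa, a complement gene, was at 57.4 ± 1.25 CPM against 14.6 ± 1.60, while Cd163, a scavenger receptor of resident macrophages, had a ratio of 0.00933 (95% interval 0.00112 to 0.0343), or 0.0140 (95% interval 0.00165 to 0.0537) without WT replicate 2. Of 6 neutrophil genes, 3 were higher, 0 lower and 3 not past, also when adjusted over the list alone (median 3.14, camera adjusted p = 0.00506, and adjusted p = 0.505 with an estimated correlation). Of 9 endothelial genes, 6 were higher, 1 lower and 2 not past (7 and 1 when adjusted over the list alone). The endothelial median was 2.39 (camera adjusted p = 0.0127, and adjusted p = 0.530 with an estimated correlation). This list call was lost with library totals (0.0916) and without 12Q replicate 1 (0.0813). Of 12 interferon-stimulated genes, 8 were higher, 0 lower and 4 not past (9 and 0 when adjusted over the list alone). The interferon median was 2.36 (camera adjusted p = 0.000801, and adjusted p = 0.530 with an estimated correlation). The endothelial, interferon and unfolded protein response lists did not pass by fry (adjusted p = 0.0986, 0.0567 and 0.0986), while fry called 5 lists that camera did not, the androgen-responsive, prostate secretory, neuroendocrine, sterol and IGF lists (0.0269, 0.0189, 0.0262, 0.0225 and 0.0277). The mean log2 fold change of endothelial genes was 2.70 without WT replicate 2 in place of 1.75, and that of interferon-stimulated genes 1.10 without 12Q replicate 2 in place of 2.29. T and NK cell genes (0 higher, 1 lower, 10 not past), B and plasma cell genes (0 and 0 of 5) and red blood cell genes (0 and 0 of 4) did not pass as lists, with camera adjusted p = 0.0589, 0.472 and 0.0851.

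The remaining lists did not pass by camera in this comparison, while fry called neuroendocrine markers lower (adjusted p = 0.0262), sterol and fatty acid genes higher (0.0225) and the IGF axis lower (0.0277). Camera gave adjusted p = 0.526 for 8 seminal vesicle secretions (1 higher, median 1.91, or 0 with bounded members). For neuroendocrine markers, of which only 3 of 11 listed had enough counts, it gave 0.0737 (2 lower). For 8 epithelial-mesenchymal transition factors it gave 0.345 (2 higher, 4 lower). It gave 0.720 for 5 adipocyte genes (1 higher, median -5.85, or -1.88 with bounded members), 0.674 for 6 urothelial genes (1 higher, 1 lower) and 0.219 for 14 sterol and fatty acid genes (1 higher). It gave 0.297 for 11 genes of the IGF axis (2 higher, 3 lower), 0.175 for 12 Notch genes (2 higher) and 0.674 for 10 Hedgehog genes (1 higher, 3 lower). Igfbp2 and Igfbp6, binding proteins of the insulin-like growth factors, had log2 fold changes of -6.54 and -7.78. Without 12Q replicate 1 they were at -7.13 and -7.04, and without 12Q replicate 2 the CPM ratio of Igfbp6 was 0.00124 (95% interval 3.1e-05 to 0.00692).

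Across the 15050 genes, edgeR called 1687 higher and 1683 lower in 12Q tumors than in WT, 50.1% of them higher. Single libraries moved this balance, with more genes higher than lower without either 12Q replicate and more lower than higher without WT replicate 1. With library totals in place of TMM the calls were 3266 higher and 1032 lower. Under library totals the median log2 fold change of all genes was 0.48 in this comparison, 0.71 in 48Q against WT and -0.19 in 12Q against 48Q, where TMM gave -0.01, 0.02 and 0.00. The total of 3370 calls dropped to 1926 without 12Q replicate 2, to 1861 without 48Q replicate 1, to 1870 without 48Q replicate 2 and to 1887 when only the 2 compared groups were fitted. No list passed with an estimated correlation, where 0 lists also had an unadjusted p under 0.05, while the preset correlation called 14 lists and fry 16.

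48Q tumors were set against the same WT libraries. By camera with the preset correlation 18 lists passed, but none with an estimated correlation, and no single gene kept its call without WT replicate 1. Cd44 stood at 452 ± 51.8 CPM against 20.4 ± 7.32 in WT, 22.1-fold higher (edgeR adjusted p = 0.00991), Notum (chromosome 11, 120653789 to 120660837) at 113 ± 14.6 against 2.09 ± 1.48 (edgeR adjusted p = 0.0108) and Lef1, a transcription factor that binds β-catenin, at 39.5 ± 7.73 against 4.27 ± 2.28 (edgeR adjusted p = 0.0269). Of 19 Wnt/β-catenin target genes, 6 were higher, 0 lower and 13 not past (12 and 0 when adjusted over the list alone). The Wnt target median was 1.77 (camera adjusted p = 2.2e-06, and adjusted p = 0.498 with an estimated correlation). Of 25 Wnt ligands and receptors, 2 were higher, 0 lower and 23 not past (7 and 0 when adjusted over the list alone), and the list did not pass (median 0.35, camera adjusted p = 0.0628). The largest increases included Gulo, the enzyme of the last step of vitamin C synthesis, at 123 ± 65.4 CPM and at least 849.6-fold above WT, where it had 0 counts. Slc1a2, a glutamate transporter gene, had a CPM ratio of 6696 (95% interval 1202 to 264514). Among the largest decreases, Aldh1l2, a mitochondrial folate enzyme gene, was at 1.90 ± 0.342 CPM against 64.5 ± 6.31, and Fgl1, a gene of a secreted fibrinogen-like protein, fell by 4.40 on the log2 scale. None of the gene calls of this comparison, here or in the next paragraphs, held without WT replicate 1, where the smallest edgeR adjusted p was 0.0669. Of the called genes above, calls were also lost (edgeR adjusted p in brackets) without 48Q replicate 1 for Lef1 (0.0910) and Fgl1 (0.0649), without 48Q replicate 2 for Lef1 (0.0843) and Fgl1 (0.106) and without WT replicate 2 for Slc1a2 (0.0542). The bound of Gulo was 529.9-fold without 48Q replicate 1. Slc1a2 was at least 1216-fold higher without WT replicate 1, which left 0 counts in WT, and its ratio was 3072 (95% interval 551 to 121355) without WT replicate 2. Fgl1 was at -3.78 without WT replicate 1.

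Seminal vesicle secretions, products of the gland next to the prostate, were found at low levels in 48Q tumors and hardly at all in WT. Which prostate lobes were taken, and whether seminal vesicle tissue was included in any sample, is not given in the sources used here, so the source of these transcripts is not known, here or between the tumor groups. All 8 tested genes were higher when adjusted over the list alone and 3 over all genes, with 0 lower and 5 not past (median 8.07, or 4.87 with bounded members, camera adjusted p = 1.9e-07, and adjusted p = 0.371 with an estimated correlation). Svs4 was at 16.5 ± 4.36 CPM with a ratio of 692 (95% interval 124 to 27365), and Sva at 5.95 ± 0.538 CPM. The ratio of Svs4 was 375 (95% interval 67.1 to 14810) without WT replicate 1, and at least 105-fold without WT replicate 2, which left 0 counts in WT. Prostate secretory products did not pass (0 higher, 0 lower of 7, and 1 and 1 when adjusted over the list alone). The secretory median was -0.43, mean 0.95 (camera direction down, adjusted p = 0.550). Pbsn was at 3101 ± 1207 CPM against 22179 ± 8535 and missed the threshold (log2 fold change -2.84, edgeR adjusted p = 0.0733). Of 21 androgen-responsive genes, 2 were higher, 2 lower and 17 not past (3 and 7 when adjusted over the list alone). The androgen-responsive median was -0.86 (camera adjusted p = 0.0238, and adjusted p = 0.498 with an estimated correlation). With library totals in place of TMM the mean log2 fold change of this list turned from -0.41 to 0.28. The median of all genes rose to 0.71 there, and the list still passed downward relative to other genes (camera adjusted p = 0.000107). Tmprss2, a protease gene induced by androgen, was at 145 ± 6.61 CPM against 1065 ± 154, and Pmepa1 at 46.9 ± 8.58 against 7.72 ± 1.77. Calls in this paragraph were lost (edgeR adjusted p in brackets) without 48Q replicate 1 for Sva (0.0970), Tmprss2 (0.0934) and Pmepa1 (0.0588), without 48Q replicate 2 for Svs4 (0.0510), Sva (0.128), Tmprss2 (0.124) and Pmepa1 (0.106) and without WT replicate 2 for Sva (0.0531) and Pmepa1 (0.0531).

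Of the 12 basal genes, 0 were called higher and 0 lower than in WT (median -0.05, mean 0.08, camera direction up, adjusted p = 0.969). Krt5 was at 72.4 ± 10.1 CPM against 51.1 ± 29.6 and Trp63 at 26.9 ± 3.79 against 38.4 ± 6.35. The luminal list passed downward without a single called member (0 higher, 0 lower of 12, and 0 and 2 when adjusted over the list alone). The luminal median was -0.98 (camera adjusted p = 0.0106, and adjusted p = 0.533 with an estimated correlation). The luminal call was lost without WT replicate 1, where the mean log2 fold change was -0.37 in place of -0.99. With library totals the luminal mean was -0.27, while the median of all genes rose to 0.71. The luminal list still passed downward there (camera adjusted p = 0.000576). Squamous genes passed upward as a list, with 6 of 17 higher, 0 lower and 11 not past (16 and 0 when adjusted over the list alone). The squamous median was 4.15, or 3.67 with bounded members (camera adjusted p = 8.9e-10, and adjusted p = 0.371 with an estimated correlation). Of 17 hair follicle genes, 8 were higher, 0 lower and 9 not past (16 and 0 when adjusted over the list alone). The hair follicle median was 6.64, or 3.83 with bounded members (camera adjusted p = 3.8e-12, and adjusted p = 0.371 with an estimated correlation). Krt36, a hair keratin gene, was at 8.46 ± 1.75 CPM and at least 58.5-fold above WT, where it had 0 counts. Cell cycle genes passed upward as a list, with 15 of 29 higher, 0 lower and 14 not past (23 and 0 when adjusted over the list alone). The cell cycle median was 2.13 (camera adjusted p = 1.1e-10, and adjusted p = 0.498 with an estimated correlation). Ccna2 was at 21.7 ± 7.37 CPM against 4.28 ± 0.957. The calls of Krt36 and Ccna2 were lost (edgeR adjusted p in brackets) without 48Q replicate 1 for Krt36 (0.0596) and Ccna2 (0.0550), without 48Q replicate 2 for Krt36 (0.0621) and Ccna2 (0.146) and without WT replicate 2 for Krt36 (0.0512) and Ccna2 (0.0534).

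Of 10 smooth muscle genes in 48Q tumors, 0 were higher, 3 lower and 7 not past (0 and 9 when adjusted over the list alone). The smooth muscle median was -2.71 (camera adjusted p = 1.3e-06, and adjusted p = 0.498 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, was at 99.9 ± 56.3 CPM against 662 ± 250.2. Of 5 skeletal muscle genes, 0 were higher, 2 lower and 3 not past (0 and 3 when adjusted over the list alone). The skeletal muscle median was -4.59 (camera adjusted p = 0.00347, and adjusted p = 0.498 with an estimated correlation). Fibroblast and matrix genes passed upward as a list, with 2 of 16 higher, 0 lower and 14 not past (4 and 1 when adjusted over the list alone). The fibroblast median was 1.05 (camera adjusted p = 0.0115, and adjusted p = 0.648 with an estimated correlation). Tnc, the tenascin C gene, was at 47.9 ± 17.9 CPM against 3.35 ± 0.828. This list was not past without WT replicate 1 (camera adjusted p = 0.118) or with library totals (0.188). Of 11 macrophage genes, 6 were higher, 0 lower and 5 not past (10 and 0 when adjusted over the list alone). The macrophage median was 2.04 (camera adjusted p = 9.0e-06, and adjusted p = 0.371 with an estimated correlation). C1qa was at 57.8 ± 0.787 CPM against 14.6 ± 1.60. Calls of Tagln, Tnc and C1qa were lost (edgeR adjusted p in brackets) without 48Q replicate 1 for Tagln (0.0742), Tnc (0.0628) and C1qa (0.0742), without 48Q replicate 2 for Tagln (0.216) and C1qa (0.0959) and without WT replicate 2 for Tagln (0.0812) and Tnc (0.0530). Neutrophil genes (2 higher, 0 lower of 6; 3 and 0 when adjusted over the list alone) passed upward as a list with a median of 3.92, or 3.42 with bounded members (camera adjusted p = 0.000896, and adjusted p = 0.498 with an estimated correlation). T and NK cell genes passed as a list with 0 called members of 11, also when adjusted over the list alone (median 1.61, camera adjusted p = 0.000345, and adjusted p = 0.498 with an estimated correlation). Mean log2 fold changes moved with single libraries. For fibroblast genes (1.11 with all) the mean was 0.73 without WT replicate 1 and 1.78 without WT replicate 2. For skeletal muscle (-3.06 with all) it was -4.68 without 48Q replicate 1. For T and NK cell genes (1.76 with all) it was 3.18 without WT replicate 2. With library totals the fibroblast mean was 1.77, while the median of all genes rose to 0.71.

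Interferon-stimulated genes passed upward as a list in 48Q tumors (3 higher, 0 lower of 12, and 7 and 0 when adjusted over the list alone). The interferon median was 1.69 (camera adjusted p = 0.000591, and adjusted p = 0.533 with an estimated correlation). The unfolded protein response list passed downward with 0 called members of 15 (0 and 2 when adjusted over the list alone). The unfolded protein response median was -1.77 (camera adjusted p = 1.7e-05, and adjusted p = 0.519 with an estimated correlation). Much of this rested on WT replicate 1, since the mean log2 CPM of the list, relative to its mean over the libraries, was 1.92 in WT replicate 1 and 0.36 in WT replicate 2 against -0.44 and -0.42 in the 48Q libraries. Without WT replicate 1 the mean log2 fold change of the unfolded protein response list was -0.78 in place of -1.82. With library totals it was -1.09, while the median of all genes rose to 0.71, and the list still passed downward (camera adjusted p = 1.6e-10). The endothelial list (1 higher, 1 lower of 9; 4 and 1 when adjusted over the list alone; median 1.61) passed upward with camera adjusted p = 0.0257, and adjusted p = 0.592 with an estimated correlation. It did not pass without 12Q replicate 1 or 2 (0.0836 and 0.0751) or with library totals (0.359). The Notch list (0 higher, 0 lower of 12; 3 and 0 when adjusted over the list alone; median 1.47) passed upward with camera adjusted p = 0.0257, and adjusted p = 0.519 with an estimated correlation. It was not past without 12Q replicate 1 or 2 (0.0642 and 0.0598) or with library totals (0.182). Immediate early genes (1 higher, 0 lower of 9; 4 and 0 when adjusted over the list alone; median 1.03) passed with camera adjusted p = 0.0238, and adjusted p = 0.519 with an estimated correlation. They did not pass without 48Q replicate 1 (0.278), without WT replicate 2 (0.0714) or with library totals (0.103). The mean log2 fold change of endothelial genes (1.14 with all libraries) was 0.65 without WT replicate 1 and 2.08 without WT replicate 2. That of Notch genes (1.21 with all) was 1.94 without WT replicate 2. That of immediate early genes (1.33 with all) was 0.51 without 48Q replicate 1. With library totals the endothelial, Notch and immediate early means were 1.79, 1.88 and 2.00, while the median of all genes rose to 0.71. By fry, the calls that held in this comparison were those of the Wnt target, seminal vesicle, squamous, hair follicle, macrophage and neutrophil lists.

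The other lists did not pass in 48Q against WT by camera or fry. Camera gave adjusted p = 0.723 for neuroendocrine markers, 0.328 for epithelial-mesenchymal transition factors (1 higher of 8), 0.281 for adipocytes, 0.267 for B and plasma cells and 0.871 for urothelium (1 higher of 6; median -0.32, mean 0.38, direction up). It gave 0.723 for red blood cells (median 0.02, mean 0.06, direction down), 0.240 for sterol and fatty acid synthesis, 0.483 for glycolysis and hypoxia genes (median -0.12, mean 0.10, direction down), 0.871 for the IGF axis (1 lower of 11) and 0.121 for the Hedgehog pathway (1 higher of 10).

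Over all genes, 595 were higher and 185 lower in 48Q tumors than in WT, 76.3% of them higher, and library totals gave 1921 higher and 83 lower. This comparison rested on single libraries. Without WT replicate 1 edgeR called 0 genes (smallest adjusted p = 0.0669), although 2972 genes had an unadjusted p under 0.05, limma-voom also called 0 and DESeq2 called 1538. The total of 780 fell to 127 without 48Q replicate 1 (122 higher and 5 lower) and to 102 without 48Q replicate 2 (98 and 4), and rose to 1215 without 12Q replicate 1 and 1188 without 12Q replicate 2. Without WT replicate 2 the balance moved the other way, higher and lower calls being closer to even than with all libraries. With all libraries DESeq2 called 2540 genes. No list passed with an estimated correlation, where 4 lists had an unadjusted p under 0.05, while the preset correlation called 18 lists and fry 6.

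**Figure D2:**
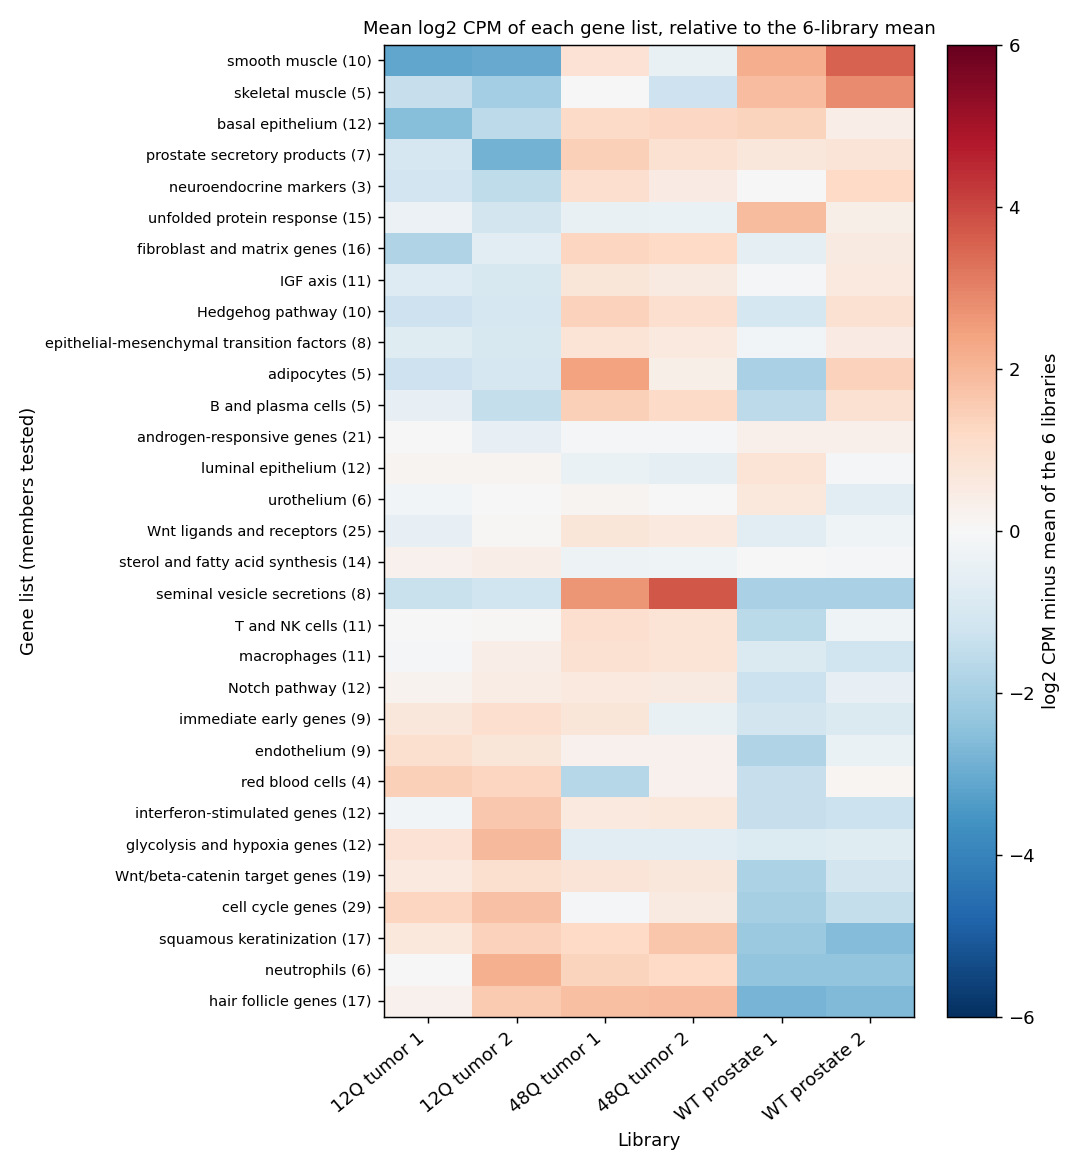
Each row is 1 of 31 gene lists with its number of tested members and each column 1 of the 6 libraries; color is the mean log2 CPM of the list minus its mean over the libraries, on a scale to 6 in both directions. Smooth muscle genes are lowest in the 12Q libraries (-3.14 and -3.04) and seminal vesicle secretions highest in the 48Q libraries (2.65 and 3.74).

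The question the series asks most directly is how 12Q tumors differ from 48Q tumors. By camera with the preset correlation the basal, fibroblast and smooth muscle lists passed downward, with 5 of 12, 3 of 16 and 5 of 10 genes called. The glycolysis and hypoxia list and the cell cycle list passed upward, with 7 of 12 and 1 of 29 called. None of these lists passed with an estimated correlation, and cell cycle, fibroblast and smooth muscle genes did not pass by fry (adjusted p = 0.101, 0.0772 and 0.0776). Wnt/β-catenin targets as a list did not differ detectably. Axin2, a direct target of β-catenin, was at 621 ± 212 CPM in 12Q and 588 ± 36.7 in 48Q (log2 fold change 0.08, edgeR adjusted p = 0.892), and Cd44 at 1155 ± 202 against 452 ± 51.8 (1.36, edgeR adjusted p = 0.0820). Of the 19 Wnt targets, 0 were higher and 0 lower (median -0.05, mean 0.13, camera direction up, adjusted p = 0.546). Of 25 Wnt ligands and receptors, 1 was higher, 1 lower and 23 not past (2 and 4 when adjusted over the list alone). The ligand and receptor median was -0.32 (camera adjusted p = 0.371). Of 21 androgen-responsive genes, 0 were higher, 1 lower and 20 not past (2 and 2 when adjusted over the list alone). The androgen-responsive median was -0.01, mean 0.02 (camera direction up but fry direction down, camera adjusted p = 0.943).

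Several basal genes were lower in 12Q than in 48Q tumors. Trp63 was at 0.111 ± 0.105 CPM against 26.9 ± 3.79 (log2 fold change -7.80, edgeR adjusted p = 0.00813) and Krt5 (chromosome 15, 101707070 to 101712891) at 0.254 ± 0.254 against 72.4 ± 10.1 (-8.08, edgeR adjusted p = 0.0165). Without 12Q replicate 1 the log2 fold changes of Trp63 and Krt5 were -7.12 and -7.34, and without 12Q replicate 2 the CPM ratios were 0.00138 (95% interval 3.5e-05 to 0.00769) and 0.00102 (95% interval 0.000123 to 0.00369). Of 12 basal genes, 0 were higher, 5 lower and 7 not past (1 and 8 when adjusted over the list alone). The basal median was -2.85 (camera adjusted p = 0.0019, and adjusted p = 0.643 with an estimated correlation). The fibroblast genes Lum, Pdgfra (chromosome 5, 75152291 to 75198204) and Lox, a collagen-crosslinking enzyme, were each called lower, Lum at 0.127 ± 0.127 CPM against 60.2 ± 4.63 and Pdgfra at 0.983 ± 0.186 against 72.8 ± 13.0 (edgeR adjusted p = 0.00813 for both). Of 16 fibroblast and matrix genes, 0 were higher, 3 lower and 13 not past (0 and 10 when adjusted over the list alone). The fibroblast median was -1.92 (camera adjusted p = 0.000172, and adjusted p = 0.695 with an estimated correlation). Of 10 smooth muscle genes, 0 were higher, 5 lower and 5 not past (0 and 8 when adjusted over the list alone). The smooth muscle median was -3.63 (camera adjusted p = 4.9e-05, and adjusted p = 0.669 with an estimated correlation). Myh11 was at 2.29 ± 0.522 CPM against 166 ± 137. The call of Myh11 was lost without 12Q replicate 1, 12Q replicate 2 or 48Q replicate 1 (edgeR adjusted p = 0.107, 0.0921 and 0.0816). Luminal genes moved the other way as a list, with 0 called members of 12 (median 0.50, camera adjusted p = 0.0463, and adjusted p = 0.720 with an estimated correlation), not past without 12Q replicate 1, 12Q replicate 2 or 48Q replicate 2 (0.152, 0.0776 and 0.0777). Endothelial genes did not pass (0 called of 9, median 0.83, camera adjusted p = 0.113).

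Glycolysis and hypoxia genes stood out among the increases, with 7 of 12 higher, 0 lower and 5 not past (10 and 0 when adjusted over the list alone). The glycolysis and hypoxia median was 2.13 (camera adjusted p = 1.3e-07, and adjusted p = 0.643 with an estimated correlation). Ldha (chromosome 7, 46845804 to 46855627), lactate dehydrogenase A, was at 971 ± 76.3 CPM against 278 ± 17.7, 3.50-fold higher (edgeR adjusted p = 0.0289), and Pkm was 4.17-fold higher (edgeR adjusted p = 0.0279). The call of Ldha was lost without 12Q replicate 1, 12Q replicate 2, 48Q replicate 1 or 48Q replicate 2 (edgeR adjusted p = 0.0535, 0.0634, 0.316 and 0.217), and that of Pkm without 12Q replicate 2, 48Q replicate 1 or 48Q replicate 2 (0.0607, 0.278 and 0.175). Among the 8 largest increases were Slc16a3, a lactate exporter, at 105 ± 58.6 CPM against 4.65 ± 0.567, Egln3, a hypoxia-induced prolyl hydroxylase, at 214 ± 233 against 5.98 ± 0.495, and the endothelial growth or tip-cell genes Apln, Angpt2 and Esm1, with log2 fold changes of 5.08, 4.25 and 4.39. Apln was at 6.07 without 48Q replicate 2. Without 48Q replicate 1 none of these 5 genes passed (edgeR adjusted p = 0.0816 for Slc16a3, 0.201 for Egln3, 0.0816 for Apln, 0.0825 for Angpt2 and 0.184 for Esm1). Without 12Q replicate 2 Apln (0.0709), Angpt2 (0.0515) and Esm1 (0.0830) did not pass, without 12Q replicate 1 Apln (0.0583) and Esm1 (0.0779), without 48Q replicate 2 Egln3 (0.146) and Esm1 (0.0974), and without WT replicate 1 or 2 Egln3 (0.0660 and 0.0661). Tm4sf1, a membrane protein gene, was at 419 ± 47.0 CPM against 17.9 ± 3.35 (log2 fold change 4.55, edgeR adjusted p = 0.00813) and kept its call when any 1 library was left out. All 29 cell cycle genes had a positive fold change, with 1 higher, 0 lower and 28 not past over all genes and 18 higher when adjusted over the list alone (median 1.41, camera adjusted p = 3.4e-10, and adjusted p = 0.643 with an estimated correlation). The called gene was Top2a, topoisomerase II alpha, at 234 ± 9.85 CPM against 78.5 ± 24.6 (edgeR adjusted p = 0.0409). It missed the threshold when any 1 of the 6 libraries was left out. The adjusted p of Top2a was 0.0501 and 0.0505 without WT replicate 1 and 2, 0.0897 and 0.0890 without 12Q replicate 1 and 2, and 0.317 and 0.108 without 48Q replicate 1 and 2.

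Secretory genes of the prostate passed downward as a list in 12Q tumors (0 higher, 2 lower of 7, also when adjusted over the list alone). The secretory median was -1.80 (camera adjusted p = 0.0231, and adjusted p = 0.643 with an estimated correlation). The secretory list was not past without 12Q replicate 2 (0.0776), and its mean log2 fold change of -2.20 was -5.22 without 12Q replicate 1 and -3.42 without 48Q replicate 2. Pbsn was at 4.23 ± 1.28 CPM against 3101 ± 1207 (log2 fold change -9.51, edgeR adjusted p = 0.0165), not past without 12Q replicate 2 (0.0514) or 48Q replicate 1 (0.0734). Seminal vesicle secretions passed downward in 12Q (0 higher, 4 lower of 8, and 0 and 7 when adjusted over the list alone). The seminal vesicle median was -6.41, or -5.51 with bounded members (camera adjusted p = 2.2e-06, and adjusted p = 0.643 with an estimated correlation). The largest decreases of all genes included Gabra4, a GABA receptor subunit gene whose counts are uncertain because of an overlapping gene, at least 276-fold lower and at 0 counts in 12Q, and the matrix or complement genes Dpt and C7, at least 103-fold and 122-fold lower. Without 48Q replicate 1 the bounds were 178-fold for Gabra4, 65.5-fold for Dpt and 76.1-fold for C7. Dpt was not past without 12Q replicate 1 or 2 (0.0586 and 0.0687) and C7 not without 12Q replicate 2 (0.0544), while Gabra4 kept its call when any 1 library was left out.

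Further lists also passed with the preset correlation. Of 8 epithelial-mesenchymal transition factors, 0 were higher and 1 lower (0 and 4 when adjusted over the list alone), with a median of -1.61 (camera adjusted p = 0.0141, and adjusted p = 0.643 with an estimated correlation). Only 3 of the 11 listed neuroendocrine markers had enough counts, and of these 0 were higher and 0 lower (0 and 1 when adjusted over the list alone). The neuroendocrine median was -2.05 (camera adjusted p = 0.0483, and adjusted p = 0.643 with an estimated correlation). The 10 Hedgehog genes, with 0 called (0 and 4 when adjusted over the list alone), had a median of -2.22 (camera adjusted p = 0.0277, and adjusted p = 0.720 with an estimated correlation). Red blood cell genes were higher as a list, with 0 called of 4 and a median of 1.85 (camera adjusted p = 0.0245, and adjusted p = 0.695 with an estimated correlation). Sterol and fatty acid genes, with 0 called of 14 (1 and 0 when adjusted over the list alone), had a median of 0.77 (camera adjusted p = 0.0141, and adjusted p = 0.643 with an estimated correlation). Immediate early genes, with 1 higher and 0 lower of 9 (2 and 0 when adjusted over the list alone), had a median of 0.94 (camera adjusted p = 0.0141, and adjusted p = 0.669 with an estimated correlation). Without 12Q replicate 2 none of these passed, with camera adjusted p = 0.0776 for the transition factor, Hedgehog, sterol and immediate early lists, 0.172 for neuroendocrine markers and 0.0899 for red blood cells. Without 12Q replicate 1, neuroendocrine markers (0.0805), red blood cells (0.0805) and Hedgehog genes (0.0927) did not pass, without 48Q replicate 1 neuroendocrine markers (0.0827) did not, and without 48Q replicate 2 immediate early genes (0.243) did not. The mean log2 fold change of red blood cell genes, 1.76, was 1.11 without 48Q replicate 1 and 3.12 without 48Q replicate 2. That of immediate early genes, 0.50, was 0.32 without 12Q replicate 2, 1.32 without 48Q replicate 1 and 0.18 without 48Q replicate 2. With library totals neuroendocrine markers (0.0623) and Hedgehog genes (0.0511) did not pass. By fry, the calls that held were those of the prostate secretory, seminal vesicle, basal, neuroendocrine, sterol and glycolysis lists.

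The remaining lists did not pass between the tumor groups by camera or fry. Camera gave adjusted p = 0.878 for squamous keratinization (2 higher, 1 lower of 17), 0.0913 for hair follicle genes (1 higher, 1 lower of 17), 0.459 for skeletal muscle, 0.304 for adipocytes (median -6.58, or -3.68 with bounded members) and 0.245 for macrophages (1 lower of 11). It gave 0.907 for neutrophils (median 0.27, fry direction down), 0.114 for T and NK cells (1 lower of 11), 0.0521 for B and plasma cells and 0.943 for urothelium (median -0.19, mean 0.12, direction up, fry direction down). It gave 0.459 for interferon-stimulated genes, 0.878 for the unfolded protein response, 0.114 for the IGF axis (3 lower of 11) and 0.825 for the Notch pathway. Igfbp2 and Igfbp6 had log2 fold changes of -5.57 and -6.94. Without 12Q replicate 1 these were -6.19 and -6.22, and without 12Q replicate 2 the CPM ratio of Igfbp6 was 0.00221 (95% interval 5.6e-05 to 0.0123).

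In all, 152 genes were higher and 475 lower in 12Q than in 48Q tumors, 24.2% of them higher, and library totals gave 62 higher and 379 lower. Scaling to luminal genes, chosen after the data were seen, gave 57 higher and 1261 lower, 4.32% of them higher. Of the 475 lower genes, 374 were also lower in 12Q than in WT, 70 were higher in 48Q than in WT and 389 were not called in 48Q against WT. Of the 152 higher genes, 135 were also higher in 12Q than in WT. The total of 627 fell to 147 and 94 without 12Q replicate 1 and 2 and to 47 and 126 without 48Q replicate 1 and 2, while DESeq2 called 2481 genes and limma-voom 1101. The split in these fits was 1 higher and 46 lower without 48Q replicate 1, 6 and 120 without 48Q replicate 2, 66 and 81 without 12Q replicate 1 and 20 and 74 without 12Q replicate 2. No list passed with an estimated correlation, where 1 list had an unadjusted p under 0.05, while the preset correlation called 14 lists and fry 6.

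**Figure D3:**
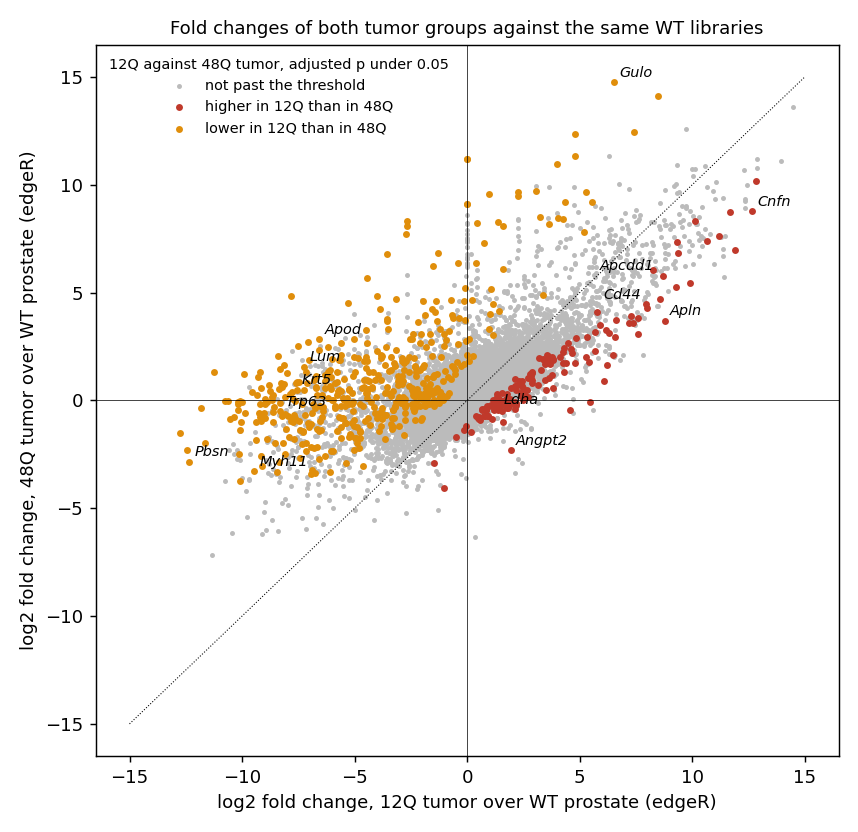
Each point is 1 of 15050 genes, with the fitted log2 fold change of 12Q against WT on the x axis and of 48Q against WT on the y axis; the 627 genes called between the tumor groups are colored by direction and the dotted line marks equal values. The 475 genes lower in 12Q had medians of -4.02 on the x axis and 0.40 on the y axis.

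Both tumor groups were compared with the same WT libraries, and 471 genes were higher and 160 lower in both, with 10 called in opposite directions. Independent lists of these sizes would share 66.7 and 20.7 genes. In 20 simulations all 6 libraries, WT included, were drawn from the WT means, and 0.05 and 0 genes were shared on average. Almost no gene was called there (on average 0.1 in 12Q alone and 0.2 in 48Q alone). A shared count near 0 was therefore fixed in advance and gives no measure of the overlap between changed groups. Fold changes correlated across genes at r = 0.665 against 0.518 in the simulations, and their covariance was 2.53 against 0.196, an excess of 2.33. The same sign was found in 71.4% of genes against 66.9% simulated. The simulated comparisons shared their WT libraries too, so the simulated covariance already includes that sharing as modelled. With 2 WT libraries the controls could not be split with 2 in each part, and no split was run. Part of the excess may still come from the shared controls, where real WT libraries vary otherwise than the simulated ones. The 631 shared calls fell to 0 without WT replicate 1, because edgeR called no gene in 48Q against WT there, to 121 and 92 without 48Q replicate 1 and 2, and DESeq2 gave 1864.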

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

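All tests of explanations in this part were chosen only after the result was seen. Their bootstrap intervals resample genes as if independent and do not measure the spread between samples. Results are listed here because 12Q and 48Q tumors differed, when tested directly, in their change from WT prostate. For 14 gene lists the difference passed camera with the preset correlation, with median log2 fold changes of 12Q over 48Q of -1.80 for prostate secretory products, -6.41 for seminal vesicle secretions, 0.50 for luminal epithelium, -2.85 for basal epithelium, -2.05 for neuroendocrine markers, 1.41 for cell cycle genes and -1.61 for epithelial-mesenchymal transition factors. The other lists were at -1.92 for fibroblast and matrix genes, -3.63 for smooth muscle, 1.85 for red blood cells, 0.77 for sterol and fatty acid synthesis, 2.13 for glycolysis and hypoxia genes, 0.94 for immediate early genes and -2.22 for the Hedgehog pathway. None of these passed with an estimated correlation.

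The 10 genes called in opposite directions against WT, each also called by edgeR between the tumor groups, had log2 fold changes of 12Q over 48Q of -5.50 for Adamts19, 4.25 for Angpt2, -9.43 for Apod, -5.51 for Fndc1, -6.84 for Lipg, -6.39 for Lox, -4.98 for Ptprt and -8.12 for Serpina3n. Gabra4 and Ms4a2 had 0 counts in 12Q and were at least 276-fold and 39.0-fold lower than in 48Q. Without 48Q replicate 1 the bound of Gabra4 was 178-fold, and without 12Q replicate 2 Apod was at -10.03. Serpina3n was at -7.36 without 12Q replicate 1, with a CPM ratio of 0.000868 (95% interval 2.2e-05 to 0.00484) without 12Q replicate 2. Several of the calls behind this set were lost when 1 library was left out, and Ms4a2 was only known to be at least 1.64-fold lower in 12Q than in WT, where it had 7 counts.

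Between the tumor groups, calls were lost (edgeR adjusted p in brackets) without 12Q replicate 1 for Adamts19 (0.0588), Lipg (0.0583) and Ms4a2 (0.0583), without 12Q replicate 2 for Adamts19 (0.0725), Angpt2 (0.0515), Fndc1 (0.0527), Lipg (0.0687) and Ms4a2 (0.0687), without 48Q replicate 1 for Adamts19 (0.108), Angpt2 (0.0825), Lipg (0.0889) and Ms4a2 (0.127), and without 48Q replicate 2 for Adamts19 (0.0861) and Ms4a2 (0.0608). In 12Q against WT they were lost without 12Q replicate 1 for Adamts19 (0.0780), Lipg (0.0601), Ms4a2 (0.0926) and Ptprt (0.0661), without 12Q replicate 2 for Adamts19 (0.133), Angpt2 (0.0827), Lipg (0.0786), Ms4a2 (0.113) and Ptprt (0.109), without 48Q replicate 1 for Adamts19 (0.143), Lipg (0.0619), Ms4a2 (0.119) and Ptprt (0.147), without 48Q replicate 2 for Adamts19 (0.149), Ms4a2 (0.0984) and Ptprt (0.121), without WT replicate 1 for Angpt2 (0.0776), Ms4a2 (0.0991) and Ptprt (0.0678), and without WT replicate 2 for Adamts19 (0.102), Angpt2 (0.0867), Lipg (0.0533), Ms4a2 (0.108) and Ptprt (0.0864). In 48Q against WT none of the 10 held without WT replicate 1 or 48Q replicate 1, and calls were lost without 48Q replicate 1 for Adamts19 (0.223), Angpt2 (0.207), Apod (0.0977), Fndc1 (0.132), Gabra4 (0.107), Lipg (0.272), Lox (0.277), Ms4a2 (0.260), Ptprt (0.0615) and Serpina3n (0.0564), without 48Q replicate 2 for Adamts19 (0.302), Angpt2 (0.128), Apod (0.0939), Fndc1 (0.215), Gabra4 (0.0544), Lipg (0.152), Lox (0.341), Ms4a2 (0.166) and Serpina3n (0.130), without WT replicate 1 for Adamts19 (0.141), Angpt2 (0.142), Apod (0.106), Fndc1 (0.105), Gabra4 (0.127), Lipg (0.142), Lox (0.124), Ms4a2 (0.164), Ptprt (0.0828) and Serpina3n (0.121), and without WT replicate 2 for Adamts19 (0.0562), Angpt2 (0.0653), Gabra4 (0.0583), Lipg (0.0598), Lox (0.0812), Ms4a2 (0.0837) and Serpina3n (0.0613).

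The basal, smooth muscle and fibroblast lists were lower in 12Q than in 48Q tumors by camera with the preset correlation, with 5 of 12, 5 of 10 and 3 of 16 genes called, but not with an estimated correlation (adjusted p = 0.643, 0.669 and 0.695), and smooth muscle and fibroblast genes not by fry (0.0776 and 0.0772). Normal prostate tissue in the 48Q samples, as the only source of these transcripts, would hold all 3 lists at equal shares of WT levels. This takes the tissue to be made up like the WT samples. As the only source, that mixture is argued against for the basal and fibroblast genes. Their median log2 fold changes of 48Q over WT lay above that of smooth muscle, by 2.66 (95% bootstrap interval over genes 2.03 to 3.36, range over the 4 library pairs 1.40 to 4.54) and 3.76 (3.27 to 4.43, pairs 3.24 to 4.53). Normal tissue together with basal or fibroblast transcripts of the tumor itself would also give such values and stays open. A single lower share of all non-luminal cells in 12Q samples, with unchanged levels per cell, is argued against by endothelial genes. Their median of 12Q over 48Q lay 4.46 above that of smooth muscle (2.60 to 5.77, pairs 3.11 to 4.78). A lower share offset by higher levels per endothelial cell would give the same value and stays open. For the smooth muscle genes, at a median of -2.71 in 48Q against WT (-3.15 to -2.36, pairs -3.89 to -1.48), a lower level in the tumor and normal tissue in the sample cannot be told apart, since both give a value below 0, and separate losses of single cell types and the polyglutamine genotype stay open, untested.

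The cell cycle and the glycolysis and hypoxia lists were higher in 12Q than in 48Q tumors by camera with the preset correlation, with 1 of 29 and 7 of 12 genes called, but not with an estimated correlation (adjusted p = 0.643 for both), and cell cycle genes not by fry (0.101). A higher epithelial share in 12Q samples, with unchanged levels per cell, would raise them by no more than luminal genes. For glycolysis and hypoxia genes this is argued against. Their median lay 1.64 above that of luminal genes (95% bootstrap interval over genes 0.617 to 2.27, range over the 4 library pairs 1.12 to 1.89). A higher share together with lower levels of luminal genes per cell would give the same value and stays open. Gene length bias is argued against for both lists, since 0% of 10000 random lists matched on length and level had a median as high as the glycolysis list (95% of them lay between -0.143 and 0.612) and 0% one as high as the cell cycle list (-0.309 to 0.329). For cell cycle genes a higher epithelial share cannot be told apart from a change within the cells, because the difference of 0.915 had an interval from -0.164 to 1.38 (pairs 0.244 to 1.43). The polyglutamine genotype, a lower oxygen supply in larger or faster-growing tumors and differences in tumor stage stay open, untested, as sizes, ages and stages are not given in the sources used here.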

How the results depend on the processing

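The scaling to luminal genes and both pairings of 48Q and WT alone were added after the data were seen; all other alternatives were planned. No named gene past the threshold turned direction under an alternative. Library totals moved the mean log2 fold change of androgen-responsive genes in 48Q against WT from -0.41 to 0.28. The median of all genes rose to 0.71 there, and this list still passed downward (camera adjusted p = 0.000107). The cause was not tested unless stated. DESeq2's size factors, both other filters and the added 2-fold minimum kept the counts of genes past the threshold within 1.5 times. Genes past the threshold in 12Q against WT moved from 3370 to 1887 in a fit of the 2 groups alone and to 775 at adjusted p under 0.01, a stricter threshold. In 48Q against WT they moved from 780 to 2004 with library totals, 2540 with DESeq2 and 44 at adjusted p under 0.01. In 12Q against 48Q they moved from 627 to 2481 with DESeq2, 1101 with limma-voom, 1318 with scaling to luminal genes and 15 at adjusted p under 0.01. Gene lists past the threshold fell from 14, 18 and 14 in the same order of comparisons to 0, 0 and 0 by camera with an estimated correlation, and from 18 to 6 and 14 to 6 by fry in the last 2. Shared calls moved from 631 to 1864 with DESeq2 and 1476 with library totals.

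Leaving out 1 library at a time gave 1861 to 2934 genes in 12Q against WT, 0 to 1215 in 48Q against WT, 47 to 866 in 12Q against 48Q and 0 to 936 shared calls. Lists ranged from 13 to 15, 16 to 21 and 6 to 17. Fewer libraries mean fewer residual degrees of freedom in each of these fits. Of the called named genes, 81 of 124 in 12Q against WT, 0 of 76 in 48Q against WT and 15 of 67 in 12Q against 48Q kept their call without any 1 library.

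With the replicate number as a replicate block, 3066, 854 and 605 genes and 15, 18 and 13 lists were past, and neuroendocrine markers in 12Q against 48Q were not (camera adjusted p = 0.0715). The labels do not say that equal numbers mark a pair, and deviations of same-numbered libraries correlated at 0.134 (WT and 12Q), -0.103 (WT and 48Q) and 0.0252 (12Q and 48Q). For 48Q against WT alone, a crossed pairing, chosen after seeing the data, gave 2985 calls as a replicate block and equal numbers gave 1182.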

Other observations

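The mast cell group in this part, and the single genes named, were chosen after their values were seen, and no explanation was tested for them. Several mast cell genes, from a list of 9 made for this purpose, were nearly absent from 12Q tumors. Against 48Q tumors 0 were higher, 5 lower and 4 not past the threshold, and against WT 0 were higher, 5 lower and 4 not past, while 48Q tumors had 1 higher and 0 lower than WT. No call between the tumor groups held without 48Q replicate 1, and calls were lost (edgeR adjusted p in brackets) without 12Q replicate 1 for Cma1 (0.0583) and Ms4a2 (0.0583), without 12Q replicate 2 for Cpa3 (0.0588), Mcpt4 (0.0514), Cma1 (0.0735) and Ms4a2 (0.0687), without 48Q replicate 1 for Cpa3 (0.105), Mcpt4 (0.0816), Tpsb2 (0.0816), Cma1 (0.165) and Ms4a2 (0.127), and without 48Q replicate 2 for Cpa3 (0.0554), Cma1 (0.0923) and Ms4a2 (0.0608). In 12Q against WT calls were lost without 12Q replicate 1 for Ms4a2 (0.0926), without 12Q replicate 2 for Cma1 (0.0687) and Ms4a2 (0.113), without 48Q replicate 1 for Cma1 (0.0766) and Ms4a2 (0.119), without 48Q replicate 2 for Cma1 (0.0709) and Ms4a2 (0.0984), without WT replicate 1 for Ms4a2 (0.0991), and without WT replicate 2 for Cma1 (0.0506) and Ms4a2 (0.108). The 1 call in 48Q, Ms4a2, was lost without 48Q replicate 1 (0.260), 48Q replicate 2 (0.166), WT replicate 1 (0.164) or WT replicate 2 (0.0837). Cpa3, a mast cell protease gene, was at 0.0370 ± 0.0523 CPM in 12Q, 7.10 ± 2.05 in 48Q and 2.66 ± 0.445 in WT, with a ratio of 12Q to 48Q of 0.00477 (95% interval 0.000577 to 0.0173, edgeR adjusted p = 0.0246). Without 12Q replicate 2 that ratio was 0.0105 (95% interval 0.00127 to 0.0381), and without 12Q replicate 1, which left 0 counts in 12Q, Cpa3 was at least 76.5-fold lower. Mcpt4 and Tpsb2 had 0 counts in 12Q and were at least 56.2-fold and 61.1-fold lower than in 48Q. Kit, a receptor gene of mast and other cells, did not differ detectably (12.1 CPM in 12Q and 9.75 in 48Q, edgeR adjusted p = 0.786).

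Ly6a, which encodes Sca-1 and marks luminal cells near the urethra, was at 686 ± 266 CPM in 12Q, 146 ± 11.7 in 48Q and 27.8 ± 3.52 in WT. Psca, another gene of these cells, was not past the threshold in any comparison.

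Among the most counted genes, Clu stood at 14194 and 8890 CPM in the 12Q libraries, 4879 and 4476 in 48Q and 53.4 and 28.5 in WT, and Glul, a glutamine synthetase gene that β-catenin drives in liver, at 7258 and 7971 CPM in 48Q, 3516 and 2137 in 12Q and 906 and 672 in WT. Tgm4, a prostate transglutaminase gene, was at 14538 CPM in 12Q replicate 1 and 598 in 12Q replicate 2. It stood at 9655 and 7509 CPM in 48Q and at 68614 and 50100 in WT. Hspa5 was at 17749 CPM in WT replicate 1 and 2774 in WT replicate 2.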
